A study of Rattus norvegicus with 192 samples.

How the data were processed

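Gene expression was measured with Affymetrix rat 3′ expression arrays in tissues of male Sprague-Dawley rats. Per the labels' protocols, the rats breathed phosphine or air in a whole-body chamber, and tissues were taken 1, 3, 6 or 24 h after exposure under ketamine and xylazine. Solid tissues were frozen in liquid nitrogen and ground, and RNA was isolated with a DNase step. Blood was drawn by heart stick and went through a separate blood RNA kit. RNA was amplified and biotinylated with a 3′ in vitro transcription kit, so the arrays read the 3′ ends of transcripts.

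The deposited values are log2 intensities, 1 value per probe set and array, made by the authors with RMA in Partek, per the submitters' processing notes; the versions are not given in the sources used here. RMA subtracts background, quantile normalizes arrays and combines the probes of a set. Which arrays were normalized together is not stated, so levels were compared within a tissue, and across tissues only as differences between PH3 and Air. The values ran from 2.038 to 14.18, and no unit other than log2 was used. Arrays give no counts, so the number of arrays per group limits the precision.

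The values covered 31139 probe sets. The 97 Affymetrix control probe sets were left out, and 31042 were tested with no filter on dim probe sets. By the platform annotation, 19063 of them name 1 gene, 572 name several and 11407 are unnamed here; no gene was named from a probe set with several. The 13438 genes carry the symbols of that annotation, and 18983 probe sets matched a gene of the GRCr8 reference by identifier. No coordinates are given, since the annotation names no build.

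The labels give every sample its tissue, exposure, time and rat number, which makes 48 groups of 3 to 5 rats. Each array of a tissue came from a different rat number, so the p-values measure the spread between rats. No 2 arrays held identical values (highest correlation 0.9957), and 0 arrays correlated best with an array of another tissue. Of the 59 rat numbers, 26 gave 1 tissue, 1 gave 2, 4 gave 4, 20 gave 5 and 8 gave 6. Rat numbers pair samples across tissues, because same-numbered samples are tissues of 1 animal. They do not pair PH3 with Air, since a rat had 1 exposure. The consensus correlation between tissues of a rat was 0.0168. As a check of the pairing, the deviation of each array from the mean of its time was correlated with those of the rats' other tissues, over the 200 probe sets that followed the rat best in those tissues, and 163 of 165 arrays matched their own rat best.

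PH3 was compared with Air of the same time in R 4.3.3 with limma 3.58.1. All arrays of a tissue entered 1 fit with a coefficient per group, so the 8 groups shared the estimate of the spread. Effects are PH3 minus Air on the log2 scale, with the SE of limma's moderated fit. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. F tests in the same fits asked whether the effect differed between the 4 times and whether the Air groups differed between times. Whether the effect differed between the 6 tissues was tested with an F test in a fit of all arrays with the rat as a random block. On simulated arrays that fit made false calls, because the tissues differ in spread. A second test was therefore added after the data were seen. It weighs the limma effect of each tissue by its own SE, after Welch, and both counts are given. Unlike the fit of all arrays, it has no block for the rat and treats the tissues as independent. A gene was represented by its brightest probe set in a tissue. Genes called with the same sign in at least 4 tissues were counted, with the overlap that independent lists of the same sizes would give.

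Lists of genes of stress, hormone, metabolic and immune responses and of markers of cell types were fixed before the data were examined, 24 to 33 per tissue. They were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and times of a tissue. Camera with an estimated correlation and fry were run beside it. List members are counted as called over all probe sets and as called adjusted over the list alone. List scores of an array, the mean over members of the difference from the Air mean of that time, were compared with exact permutation tests, two-sided.

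The genes to be named were also fixed by a rule: genes past adjusted p under 0.05 whose PH3 arrays all lay beyond all Air arrays, taking the 6 largest rises and 6 largest falls at the time with most calls in a tissue and 2 of each at other times. To these came up to 4 called members of each list, up to 12 genes shared by most tissues, and the 4 genes per tissue with the smallest p for a difference between Air times. Genes outside the rule are named as chosen after their values were seen.

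RNA quality was read from the control probe sets of Gapdh and beta-actin as the 3′ minus 5′ difference, a mean of both genes called the 3′ index here; a high index goes with degraded RNA or weak amplification. Arrays more than 5 robust SDs from their tissue on the first or second principal component or on the 3′ index were counted as standing apart.

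Alternatives set beforehand were a mean-variance trend with robust moderation, a fit of the 2 groups alone, a fit of all arrays with the rat as replicate block, the brighter 50 percent of probe sets, quantile normalization again, array medians subtracted, 1 probe set per gene, other list tests, other thresholds for shared genes, and leaving out each rat. Chosen after seeing the data were the 3′ index as a covariate, leaving out arrays that stand apart, other Air controls for the lung at 3 h, Air times without the lung 3 h or brain stem 24 h arrays, the tissue test without blood, and the test with the spread of each tissue. The olfactory bulb at 3 and 6 h was also fitted with 2 ranges of rat numbers as a block.

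The steps were tested on simulated arrays with the real groups and the real spread of each probe set. Of probe sets changed by 1 log2 unit at 1 h, limma recovered 22.4% in blood, 97% in brain stem, 74.6% in heart, 91% in kidney, 91% in lung and 95.5% in olfactory bulb; of those changed by 0.5, it recovered 0%, 70.1%, 10.4%, 50.7%, 49.3% and 55.2%. Between 2 and 12 unchanged probe sets were called in these contrasts. In the test of tissues at 1 h, the fit of all arrays called 460 unchanged probe sets and the test with the spread of each tissue called 13. The simulated noise was independent between probe sets and arrays, so real arrays can give more false calls. Other splits of the real rats gave up to 768 calls at 24 h with the spread of each tissue, and up to 2189 in blood at 24 h in limma.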

Results

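Rats breathed phosphine (PH3), a fumigant gas that blocks cytochrome c oxidase, at 660 ppm for 25 min, which the labels give as 16,500 ppm×min and 0.71 × LCt50, or they breathed air. Gene expression was read at 1, 3, 6 and 24 h in blood, brain stem, heart, kidney, lung and olfactory bulb, 31 to 33 arrays each, under 59 rat numbers in all. Groups held 4 rats, except 3 in blood Air at 24 h and 5 in olfactory bulb Air at 1 h. Of 31042 probe sets, limma called 95 in brain stem, 284 in heart, 729 in kidney, 1317 in lung, 1 in olfactory bulb and 0 in blood at 1 h. At 3 h it called 5, 2, 94, 3071, 0 and 0 in the same order. Effects below are PH3 minus Air in log2 units ± SE, and p is adjusted over all probe sets unless stated.

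**Figure D1:**
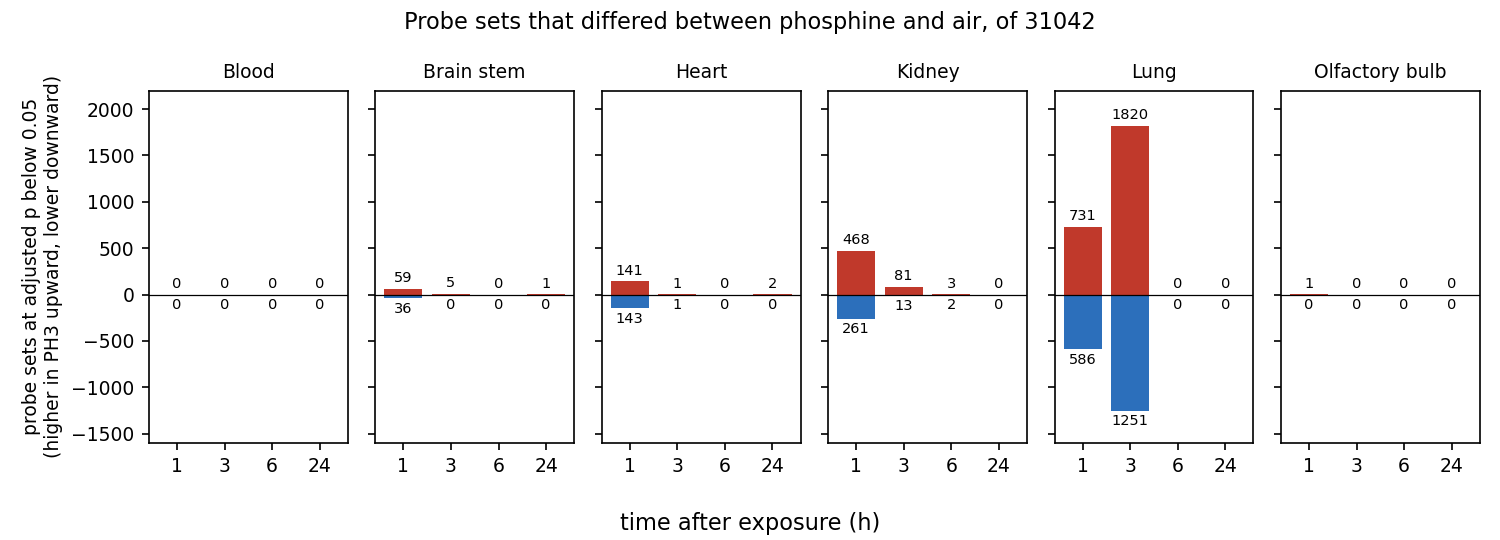
Probe sets called higher and lower in PH3 than in Air (vertical axis, count) per tissue and hours after exposure; each bar is 1 contrast of 3 to 5 rats per group. Lung at 3 h has the tallest bars, 1820 higher and 1251 lower.

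In the heart at 1 h, among the genes named by the rule, those switched on within minutes of a stimulus rose most. Atf3, a transcription factor of cell stress, Nr4a3 and Nr4a1, nuclear receptors without a known hormone, and Fosb, a partner in the AP-1 transcription factor, rose. Mt2A, a metal-binding protein, and Gal, the peptide galanin, rose too. Meox2 and Aplnr, which are active in vessel walls, Mycn, a driver of growth, and Cxcr4, a chemokine receptor, fell. Effects were 4.03 ± 0.545 for Atf3 (adjusted p = 1.8e-04), 3.47 ± 0.465 for Nr4a3, 3.30 ± 0.466 for Fosb, 3.06 ± 0.418 for Nr4a1, 2.63 ± 0.441 for Mt2A (adjusted p = 0.00191) and 2.44 ± 0.392 for Gal. They were -1.93 ± 0.244 for Meox2 (adjusted p = 9.1e-05), -1.93 ± 0.344 for Aplnr, -1.86 ± 0.262 for Mycn and -1.48 ± 0.215 for Cxcr4. Lurap1l, a relative of an NF-κB activator, and RGD1309362 had effects of -1.72 and -1.42. Among inflammatory genes, Ptgs2, which makes prostaglandins, rose by 2.34 ± 0.529 (adjusted p = 0.025), Cxcl1, which draws neutrophils, by 1.99, and Socs3 and Nfkbiz, which tune cytokine signals, by 1.83 and 1.78. Of 26 genes of acute inflammation, 20 were positive and 6 called higher (9 over the list alone; camera adjusted p = 4.8e-08, adjusted p = 0.26 with an estimated correlation and 0.119 in fry). Of 26 immediate early genes, 25 had a positive effect, and 11 were called higher (22 adjusted over the list alone; camera adjusted p = 5.4e-32, adjusted p = 0.0366 with an estimated correlation). Of 22 glucocorticoid targets, which cortisol-like hormones induce, 6 were called higher (11 over the list alone; camera adjusted p = 4.1e-14, adjusted p = 0.0075 with an estimated correlation). Red cell markers, a sign of blood in the sample, had a median effect of 0.25 and were all 10 positive (camera adjusted p = 0.006, adjusted p = 0.759 with an estimated correlation, lost without Air Rat353). The list of endothelial markers was also called (camera adjusted p = 0.0236), but not with an estimated correlation, in fry or without PH3 Rat357. The calls were 141 higher and 143 lower, 205 and 119 with array medians subtracted, 124 and 197 among the brighter 50 percent of probe sets, and 172 and 244 with the 3′ index as a covariate, so which direction leads depends on the setting. They were 9 with the groups of 1 h alone, 733 in the fit with the rat as replicate block, 177 without the arrays that stand apart, 85, 98, 112, 118, 131 and 169 without PH3 Rat343, PH3 Rat357, Air Rat352, Air Rat353, Air Rat345 and Air Rat354 in turn, and 766 without PH3 Rat351.

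Later in the heart few genes passed. Dach1, a transcription factor of growing vessels, fell at 3 h, and a second probe set of Fkbp5, a partner of the glucocorticoid receptor, rose. Dancr, a noncoding RNA, rose at 24 h with 1 unnamed probe set. The effects were -1.13 ± 0.185 (adjusted p = 0.023), 1.22 ± 0.196 (adjusted p = 0.023) and 1.06 ± 0.177 (adjusted p = 0.0296), and the second Fkbp5 probe set was chosen after the values were seen. At 6 h limma called 0, with 982 at an unadjusted p under 0.05. The calls at 3 h and 24 h were 0 with the groups of that time alone. The 3 h calls fell to 0 without PH3 Rat359, Rat361 or Rat399 or Air Rat365 or Rat370, with 1 left without Air Rat400. The 24 h calls fell to 0 without Air Rat328 or Rat502 and to 1 without PH3 Rat333 or Rat341 or Air Rat335, and were 5 without PH3 Rat325. Without PH3 Rat326 or Air Rat340, 3 and 2 were called, with 1 of the original 2 among them.

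In the kidney at 1 h, stress genes rose and a chemokine gene fell. Fosb and Atf3, the stress transcription factors, Gdf15, a hormone of damaged cells, Nr4a1 and Nr4a3 rose, as did Maff, a partner of stress transcription factors. Ccl2, which draws monocytes, A4galt, which builds glycolipids, Ihh, a growth signal of tubules, and Jag1, a Notch ligand, fell, with Evi2a, a membrane protein. Effects were 3.49 ± 0.216 for Fosb (adjusted p = 2.2e-11), 3.39 ± 0.264 for Atf3 (adjusted p = 2.7e-09), 2.83 ± 0.218 for Gdf15 (adjusted p = 2.7e-09), 2.76 ± 0.232 for Nr4a1, 2.11 ± 0.179 for Nr4a3 and 1.97 ± 0.212 for Maff. They were -1.61 ± 0.358 for Ccl2 (adjusted p = 0.0109), -1.46 for Evi2a, -1.40 for A4galt, -1.35 for Ihh, -1.10 for Jag1 and -0.97 for LOC100910497. Cdkn1a, which stops the cell cycle, Tnfrsf12a, a receptor of injured tubules, and Pdk4, which spares glucose, rose by 1.83, 1.69 ± 0.239 and 1.39. Of 26 immediate early genes, 8 were called higher (11 over the list alone; camera adjusted p = 6.5e-19, adjusted p = 0.00626 with an estimated correlation). Of 22 glucocorticoid targets, 11 were (15 over the list alone; 8.6e-18 and adjusted p = 5.1e-04 with an estimated correlation). Of 26 targets of ATF4, the transcription factor of the integrated stress response, 6 were (7 over the list alone; 1.3e-07 and adjusted p = 0.00831 with an estimated correlation). This list was also called in heart and lung at 1 h (camera adjusted p = 7.3e-07 and 0.00304), in both lost with an estimated correlation only. In heart at 3 h it was called too (camera adjusted p = 0.00114), but not with an estimated correlation or in fry. Insig1, Sqle and Dhcr7 of cholesterol synthesis rose by 0.89, 0.61 and 0.56, 3 of 15 called (6 over the list alone; camera adjusted p = 2.9e-05, adjusted p = 0.428 with an estimated correlation). Red cell markers, all 10 positive, included called Alas2 at 1.38 and Ahsp at 0.82 (camera adjusted p = 0.00271, adjusted p = 0.068 with an estimated correlation). The 729 calls were 468 higher and 261 lower; they were 121 with the groups of 1 h alone, 214 with the rat as replicate block, and 396 and 454 without PH3 Rat343 and Rat357.

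At 3 h and 6 h in the kidney single genes passed, with Gdf15 and Scarb1 higher at each time. Olr1, a receptor for oxidized lipoprotein, Gdf15 and Ddit3, a switch toward cell death under stress, rose at 3 h. Scarb1, which takes up cholesterol from HDL, rose at 6 h, with Gdf15, while Igsf5, a junction protein, fell. The 3 h effects were 1.82 ± 0.25 for Olr1 (adjusted p = 2.5e-04), 1.74 ± 0.218 for Gdf15 (adjusted p = 6.5e-05) and 1.29 ± 0.181 for Ddit3 (adjusted p = 2.9e-04); A4galt and Ppp2r2b, a phosphatase subunit, fell by 1.00 and 0.77. The 6 h effects were 1.29 ± 0.218 for Gdf15 (adjusted p = 0.0195), 0.88 ± 0.121 for Scarb1 (adjusted p = 0.00103) and -0.60 ± 0.104 for Igsf5 (adjusted p = 0.0254). Scarb1 at 3 h, chosen after its value was seen, had the smallest p, with 1.58 ± 0.121 (adjusted p = 7.4e-09). Markers of the adrenal gland, where Scarb1 is abundant, went the other way at 3 h, with a median of -0.21, 7 of 9 negative and 0 called (camera adjusted p = 0.0423, adjusted p = 0.387 with an estimated correlation; lost without PH3 Rat359 or Rat399 or Air Rat355 or Rat400). Of 26 ATF4 targets at 3 h, 2 were called higher (7 over the list alone; camera adjusted p = 6.9e-07, adjusted p = 0.0115 with an estimated correlation). The calls were 81 higher and 13 lower at 3 h and 3 higher and 2 lower at 6 h, where the 2 not named above are a second Scarb1 probe set (1.00) and an unnamed one (-1.60), chosen after the values were seen. At 24 h limma called 0, with 1949 at an unadjusted p under 0.05. The 3 h calls were 14 with the groups of 3 h alone, 31 with the rat as replicate block, 48 without PH3 Rat361 or Air Rat400, and 32 without PH3 Rat363, whose only array matched the other tissues of Rat368. The 5 calls at 6 h were 0 with those 2 groups alone, 2 without PH3 Rat391 and 3 without PH3 Rat375 or Rat381 or Air Rat377 or Rat394. That of Gdf15 was also lost without Air Rat382, and that of Igsf5 without PH3 Rat387.

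In the lung at 1 h, targets of glucocorticoids rose. Mt2A, Fkbp5 and Map3k6, a stress kinase, rose, with Il1a, an alarm cytokine, Maff and Abra, an actin-linked activator of muscle genes. Pdk4 and Pfkfb3, which steer glucose use, rose as well. Spns2, which exports sphingosine-1-phosphate from endothelium, Ahr, a receptor for foreign compounds, and the chemokines Ccl2 and Ccl7 fell. Effects were 2.59 ± 0.267 for Mt2A (adjusted p = 1.4e-06), 2.49 ± 0.414 for Abra (adjusted p = 3.5e-04), 2.38 ± 0.279 for Fkbp5 (adjusted p = 6.0e-06), 2.15 for Map3k6, 2.02 ± 0.394 for Il1a, 1.97 ± 0.171 for Maff (adjusted p = 1.5e-07), 1.86 for Pdk4 and 1.84 for Pfkfb3. They were -1.29 ± 0.17 for Spns2 (adjusted p = 2.0e-05), -1.23 ± 0.204 for Ahr (adjusted p = 3.1e-04), -1.31 for Ccl2 and -0.89 for Ccl7. Of 22 glucocorticoid targets, 12 were called higher (16 over the list alone; camera adjusted p = 1.2e-19, adjusted p = 0.004 with an estimated correlation). Of 26 immediate early genes, 5 were (7 over the list alone; 5.8e-05 and adjusted p = 0.361 with an estimated correlation), and Atf3 and Fosb rose by 1.11 and 1.38. Of 12 endothelial markers, 5 were positive and 7 negative, Sox17 (0.72) and Cldn5 (0.63) called higher and Kdr (-0.49) lower (3 and 1 over the list alone), and the list was not called (camera adjusted p = 0.353, adjusted p = 0.921 with an estimated correlation). Red cell and platelet markers had median effects of 0.37 and 0.30 (camera adjusted p = 0.0174 and 0.0233, adjusted p = 0.612 and 0.706 with an estimated correlation), the first lost without PH3 Rat357 or Air Rat353 and the second without PH3 Rat343 or Rat357 or Air Rat352, Rat353 or Rat354. B cell markers went the other way, with a mean score of -0.408 in PH3 (camera adjusted p = 0.0269). That call was lost with an estimated correlation, in fry and without PH3 Rat343 or Rat350 or Air Rat345 or Rat354. The calls were 731 higher and 586 lower, 519 with the groups of 1 h alone, 384 with the rat as replicate block, 769 without PH3 Rat343 and 863 without Air Rat352.

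At 3 h the lung gave the most calls of all contrasts, beside a difference in RNA quality between the groups. Il1r2, a decoy receptor for IL-1, Fgf7, a growth factor for epithelium, and Ccl11, which draws eosinophils, were higher in PH3, as were Kcnj8, a potassium channel of vessel walls, Sh2d1a, a lymphocyte adaptor, and Gal. Hmcn1 and Hspg2, large proteins of the matrix, Bhlhe40, a clock repressor, and Pde7b, which breaks down cAMP, were lower. S100a8, S100a9 and Mmp8 of neutrophils were higher. Effects were 1.78 ± 0.243 for Il1r2 (adjusted p = 1.7e-04), 1.66 ± 0.324 for Fgf7 (adjusted p = 0.00257), 1.61 for Ccl11, 1.57 for Kcnj8, 1.54 for Sh2d1a, 1.54 for Gal, -1.09 ± 0.191 for Hmcn1 (adjusted p = 0.00127), -1.08 for Hspg2, -0.99 for Bhlhe40, -0.96 for Pde7b, -0.94 for Adam4, a membrane protease, and -0.94 for C3h20orf96. S100a8, Mmp8 and S100a9 had 1.41, 1.36 and 1.21. Of 10 neutrophil markers, 4 were called higher (5 over the list alone; camera adjusted p = 5.4e-04, adjusted p = 0.537 with an estimated correlation). Of 16 T cell markers, 4 were (4 over the list alone; 9.6e-04 and adjusted p = 0.537 with an estimated correlation). The 3′ index was 0.445 ± 0.0776 (SD) in Air and 0.178 ± 0.065 in PH3 (exact permutation p = 0.0286, adjusted p = 0.686 over 24 such tests). This p is the smallest that 4 against 4 rats allow, so 1 such difference alone could not pass the adjustment, whatever its size. With the index as a covariate 4 of the 3071 calls were left, and the PH3 arrays set against the Air arrays of the other times gave 431; both were chosen after the data were seen. With those controls Fgf7 had 0.47, Ccl11 0.80, Kcnj8 0.72, Sh2d1a 0.28, Hspg2 -0.25, Pde7b -0.35, Adam4 -0.10, S100a8 0.43, Mmp8 0.60 and S100a9 0.52, and C3h20orf96 turned to 0.01, so these effects rest largely on the Air 3 h arrays. The calls were 801 with the groups of 3 h alone, 188 higher and 200 lower with the rat as replicate block, 1739 without Air Rat355, 1876 without PH3 Rat361 and 1356 without PH3 Rat368. At 6 h and 24 h limma called 0, with 1536 and 1906 at an unadjusted p under 0.05. The smallest p at 6 h was that of Eno2, a glycolysis enzyme (0.84, adjusted p = 0.0722), and without Air Rat340 limma called 3 at 24 h.

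**Figure D2:**
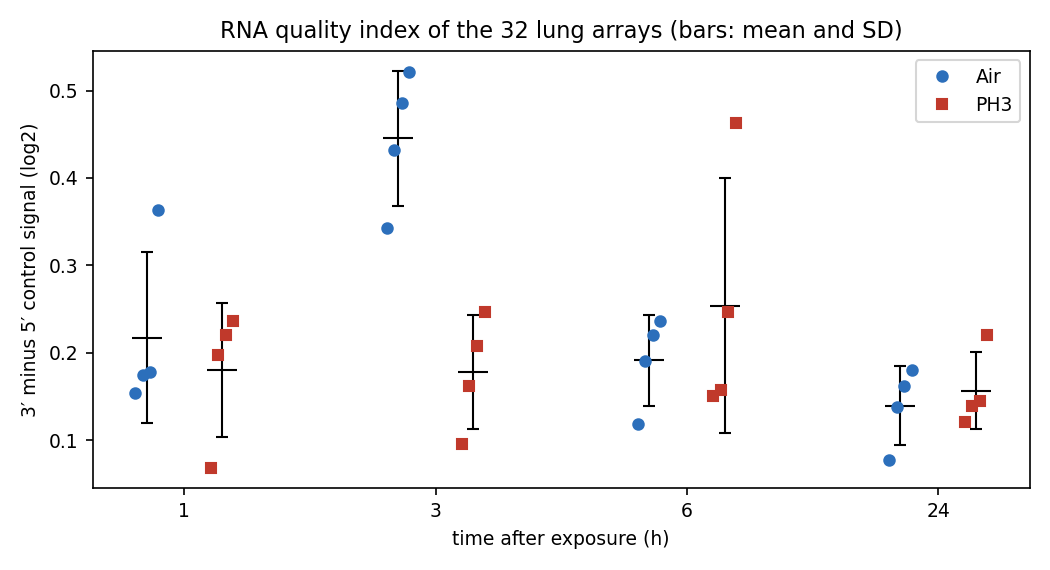
The 3′ minus 5′ index (vertical axis, log2 units) of each lung array by exposure and time; each point is 1 rat, bars are mean and SD. Of the 8 groups, the 3 h Air rats have the highest mean, 0.445.

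In the brain stem at 1 h, genes induced by glucocorticoids rose. Sgk1, a kinase of ion transport, Pdk4 and Nfkbia, the inhibitor of NF-κB, rose, with Tmem252, a membrane protein, Phactr3, a phosphatase regulator, and Pcdh20, an adhesion protein. Tnfrsf11b, a decoy receptor for bone and vessel signals, Cxcr4, Car4, a carbonic anhydrase of capillaries, and Tlr2, a receptor for microbes, fell. Effects were 2.37 ± 0.342 for Tmem252 (adjusted p = 7.5e-04), 1.93 ± 0.406 for Sgk1 (adjusted p = 0.0265), 1.75 ± 0.276 for Pdk4 (adjusted p = 0.00173), 1.38 for Phactr3, 1.31 ± 0.184 for Pcdh20 and 1.29 ± 0.243 for Nfkbia. They were -1.53 ± 0.157 for Tnfrsf11b (adjusted p = 5.5e-06), -1.28 ± 0.209 for Cxcr4, -0.90 for Car4, -0.79 for Tlr2, -0.76 for Lef1, a Wnt factor, and -0.70 for G0s2, which slows fat breakdown. Of 22 glucocorticoid targets, 9 were called higher (16 over the list alone; camera adjusted p = 4.3e-29, adjusted p = 0.00551 with an estimated correlation). Of 12 endothelial markers, 10 were negative at 1 h and 11 positive at 24 h, with 0 called (camera adjusted p = 0.00103 and 6.3e-04, adjusted p = 0.616 for each with an estimated correlation; the second lost without PH3 Rat341). At 3 h, Fkbp5 rose by 0.87 ± 0.141 (adjusted p = 0.0217) and Gpatch4, a nucleolar protein, by 0.78 ± 0.135 (adjusted p = 0.0289), each also in a second probe set (0.78 and 0.91), with 1 unnamed. Of 6 metallothionein and metal response genes at 3 h, 0 were called (3 over the list alone; median 0.13, camera adjusted p = 0.00108, adjusted p = 0.0251 with an estimated correlation). At 24 h, respiratory chain and ATP synthase subunits had a median effect of -0.11, 22 of 24 negative (camera adjusted p = 2.1e-06, adjusted p = 0.677 with an estimated correlation), and 1 unnamed probe set was called higher. Of 13 subunits of cytochrome c oxidase, 10 were negative, median -0.05 and 0 called (camera adjusted p = 0.0474, adjusted p = 0.767 with an estimated correlation; lost without PH3 Rat325 or Rat333 or Air Rat502). At 6 h limma called 0, with 904 at an unadjusted p under 0.05. The 1 h calls, 59 higher and 36 lower, were 18 with those groups alone, 18 with the rat as replicate block, 32 without PH3 Rat343 or Air Rat352, 42 without PH3 Rat357 and 61 without Air Rat353. The 5 calls at 3 h were 0 with those groups alone and without PH3 Rat358 or Air Rat370, 1 without PH3 Rat368 or Rat399 or Air Rat365 or Rat400, 3 without PH3 Rat359 and still 5 without Air Rat355, 4 of the original 5 among them. At 24 h the call was lost without PH3 Rat325 or Rat333 or Air Rat328, Rat340 or Rat502, with 1 other called without Rat333 or Rat340, and 2 and 3 were called without PH3 Rat341 and Rat326, and at 6 h 1 was called without PH3 Rat375.

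In the olfactory bulb, groups of genes shifted in camera while single genes did not pass. Interferon response genes, which limit viruses, had positive effects at 1 h and 24 h, and markers of neutrophils and red cells at 3 h. The interferon list was also called at 3 h (camera adjusted p = 0.0497). That call was lost with an estimated correlation, with all probe sets, in fry and without any 1 of 5 rats. Of 19 interferon genes, 0 were called (11 over the list alone at 1 h and 13 at 24 h; medians 0.74 and 0.88; camera adjusted p = 5.6e-14 and 1.9e-22, adjusted p = 0.591 and 0.456 with an estimated correlation). Of 10 neutrophil markers at 3 h, 0 were called (5 over the list alone; median 0.75, camera adjusted p = 4.8e-04, adjusted p = 0.591 with an estimated correlation), and red cell markers had a median of 0.62 (1.7e-06 and adjusted p = 0.591 with an estimated correlation). Without PH3 Rat512 neither list was called, so both calls rest on 1 rat. Genes of NRF2, the sensor of oxidants, and of the unfolded protein response had medians of 0.26 and 0.25 at 6 h (camera adjusted p = 7.2e-05 and 4.4e-06, adjusted p = 0.591 for each with an estimated correlation). Single calls were 1 unnamed probe set at 1 h (0.34) and 0 at 3, 6 and 24 h, with 1599, 2351, 3055 and 1271 at an unadjusted p under 0.05 in limma. The smallest p among genes at 1 h was that of Angptl4, which slows lipoprotein lipase (1.18, adjusted p = 0.425), and at 3 h that of Pnpla2, a fat lipase (0.83, adjusted p = 0.201). The 1 h call was lost without any 1 of the rats but PH3 Rat506, with 1 other called without Air Rat472. Limma called 3 at 1 h without PH3 Rat506, 8 and 1 at 3 h without PH3 Rat399 and Air Rat400, and 8 at 6 h without PH3 Rat387, and with the rat as replicate block the counts were 7, 36, 29 and 3.

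In blood no gene passed at any time. B cell markers were lower at 1 h in camera, and markers of neutrophils, which leave the marrow early under stress, were higher at 3 h and lower at 6 h (adjusted p = 0.726 for each with an estimated correlation). Limma called 0 at 1, 3, 6 and 24 h, with 2588, 910, 1315 and 2018 at an unadjusted p under 0.05. The smallest p at 1 h was that of Fcer2, an IgE receptor of B cells (-2.71 ± 0.476, adjusted p = 0.0585). All 8 B cell markers were negative at 1 h, with a median of -0.90 and 0 called (5 over the list alone; camera adjusted p = 2.4e-04, adjusted p = 0.726 with an estimated correlation). Their mean score differed by -0.837 (exact permutation p = 0.143, adjusted p = 0.207), with PH3 Rat351 at 0.132. Neutrophil markers had medians of 0.44 at 3 h and -0.52 at 6 h, and NK cell markers -0.45 at 24 h (camera adjusted p = 0.00192, 0.0287 and 0.0287, adjusted p = 0.726 for each with an estimated correlation). These calls were lost without PH3 Rat368 at 3 h, without PH3 Rat387 or Air Rat382 or Rat388 at 6 h, and without PH3 Rat326 or Rat341 or Air Rat328 at 24 h. The residual SD of a probe set had a median of 0.491 in blood, against 0.153 to 0.25 in the other tissues. Without PH3 Rat351 limma called 129 at 1 h, and without PH3 Rat333 it called 172 at 24 h. With the rat as replicate block, which pools the smaller spread of other tissues into blood, the counts were 6015, 1987, 3322 and 5686.

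At 1 h, 4 genes were called higher in 4 tissues, which were brain stem, heart, kidney and lung. They are Tmem252, Mt2A, Fkbp5 and Cebpb, a transcription factor of acute responses. In brain stem, heart, kidney and lung their effects were 2.37, 1.62, 1.44 and 1.84 for Tmem252, 0.99, 2.63, 0.59 and 2.59 for Mt2A, 1.18, 1.41, 1.16 and 2.38 for Fkbp5, and 0.65, 1.20, 1.02 and 0.56 for Cebpb. In olfactory bulb they were 0.67, 0.18, 0.06 and 0.23, and in blood -0.25, 0.26, 0.78 and 0.63. In at least 3 tissues 33 genes were called, among them Atf3, Fosb, Nr4a3, Maff and Map3k6 in heart, kidney and lung, Cdkn1a and Pdk4 in brain stem, kidney and lung, and Errfi1, a brake on the EGF receptor, in brain stem, heart and lung. Kidney and lung shared 62 genes called higher, where independent lists would share 5.81, and 35 called lower against 3.81; heart and lung shared 33 against 2.11 and 27 against 2.01. These tissues come from the same rats, so the lists are not independent. Mean scores of the glucocorticoid targets differed between PH3 and Air by 0.706 in brain stem, 0.81 in heart, 0.706 in kidney and 1.01 in lung (exact permutation p = 0.0286 each, the smallest 4 against 4 rats allow; adjusted p = 0.0531 over 13 tests). They differed by 0.116 in blood (exact p = 0.114) and 0.226 in olfactory bulb (exact p = 0.206), where 19 of the 22 were positive and 0 called (camera adjusted p = 0.00164, adjusted p = 0.591 with an estimated correlation, lost without PH3 Rat482). The olfactory bulb arrays of 1 h came from rats that gave none of the other tissues. Its smaller effects thus cannot be told apart from a difference between sets of rats. At 3 h 0 genes were called in 4 tissues and 1, Fkbp5, in 3.

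**Figure D3:**
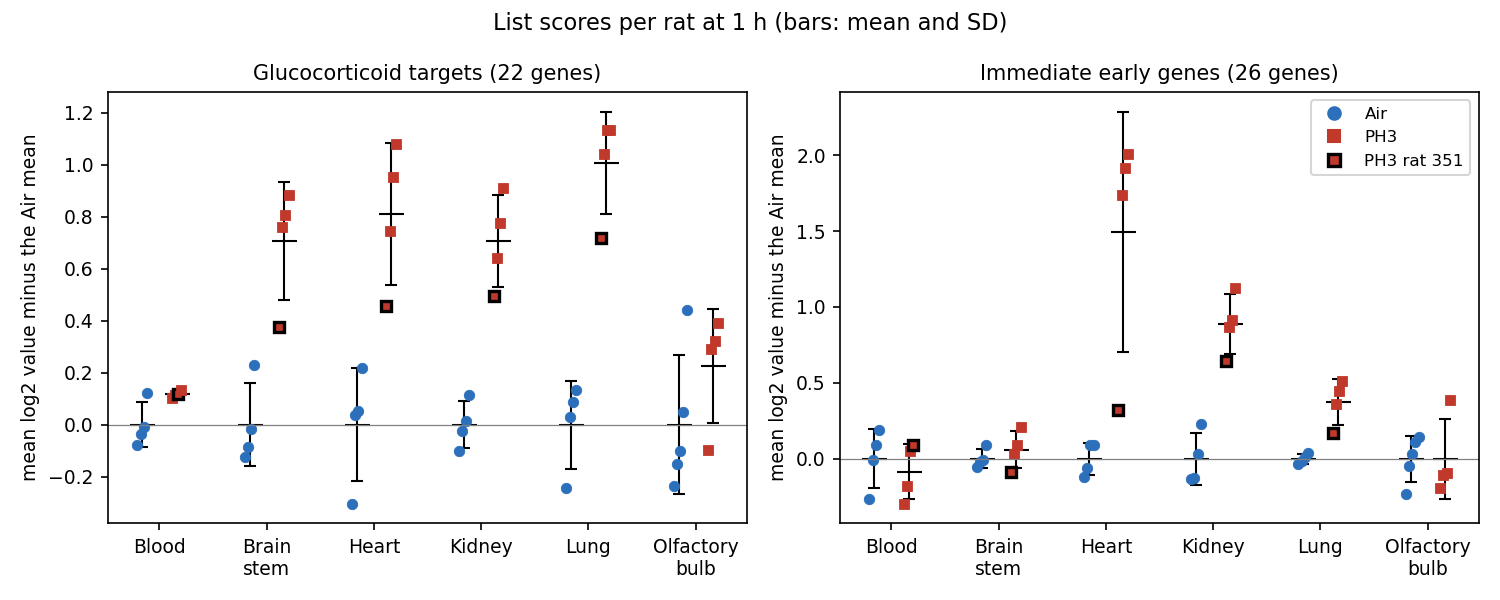
Mean score of fixed gene lists (vertical axis, log2 units relative to the Air mean) at 1 h per tissue; each point is 1 rat, PH3 or Air, with Rat351 outlined, and bars are mean and SD. Glucocorticoid target scores of PH3 and Air differ by 1.01 in lung and 0.226 in olfactory bulb, whose 1 h rats gave none of the other tissues.

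The effect of phosphine depended on time for single genes in 4 tissues. Gdf15 and Scarb1 in kidney, Fkbp5 in lung, Tnfrsf11b in brain stem and Atf3 in heart were among the genes whose effect differed between the times. Their adjusted p were 3.8e-06, 1.2e-04, 2.1e-05, 4.3e-05 and 0.0419. In all, 22 probe sets in brain stem, 36 in heart, 152 in kidney and 1497 in lung had such a difference, and 0 in blood and olfactory bulb, where limma gave 1573 and 2184 at an unadjusted p under 0.05. With the 3′ index as a covariate the count was 535 in lung, where Air and PH3 differed in the index at 3 h, and 95 in heart, and Fkbp5 in lung stayed called (adjusted p = 9.2e-05). Without PH3 Rat351 the counts were 42 in brain stem, 186 in heart and 280 in kidney, and without PH3 Rat343 they were 11 in brain stem and 10 in heart. In brain stem they were 11, 12 and 14 without Air Rat352, PH3 Rat357 and PH3 Rat350. In heart they were 12, 15, 20 and 22 without Air Rat352, Rat353, Rat345 and Rat354, 16, 19 and 22 without PH3 Rat357, Rat350 and Rat341, and 67 without PH3 Rat368. In blood limma called 2 without PH3 Rat351. In the lung it was 997 without PH3 Rat357 and 908 without PH3 Rat368.

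**Figure D4:**
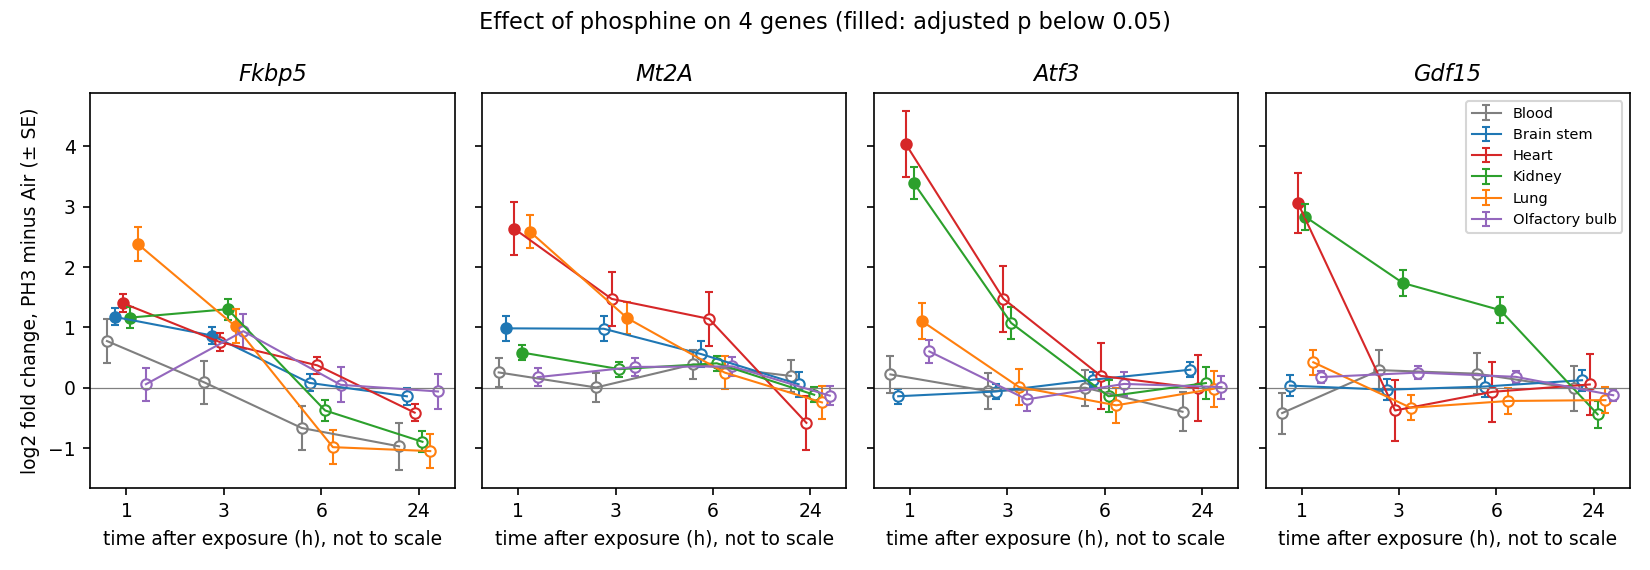
Effect of PH3 (vertical axis, log2 PH3 minus Air ± SE) on named genes by tissue and hours after exposure (horizontal axis); each point is a contrast of 3 to 5 rats per group. Gdf15 in kidney goes from 2.83 at 1 h to 1.29 at 6 h.

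The effect at 1 h also depended on the tissue. The olfactory bulb arrays of that time came from rats that gave no other tissue, so there tissue and set of rats cannot be told apart. Atf3, Fosb, Gdf15, Maff and Mt2A rose more in some tissues than in others, and Scarb1 and Olr1 did so at 3 h. With the spread of each tissue, a test chosen after the data were seen, adjusted p were 5.7e-15 for Atf3, 5.7e-15 for Fosb, 2.1e-13 for Gdf15, 5.9e-10 for Maff, 5.0e-08 for Mt2A, 5.6e-07 for Meox2, 1.4e-06 for Spns2, 1.0e-05 for Tnfrsf11b and 0.00135 for Fkbp5. At 3 h they were 2.9e-11 for Scarb1 and 7.1e-04 for Olr1. This test called 959 probe sets at 1 h, 94 at 3 h, 2 at 6 h and 0 at 24 h. It treats the tissues as independent, although most come from the same rats. The fit of all arrays gave 1981, 243, 235 and 901, or 1320, 372, 12 and 64 with array weights, and on simulated arrays it called 460 unchanged probe sets at 1 h. Its counts at 1 h were 1282 without PH3 Rat343, 3282 without PH3 Rat351 and 1089 without PH3 Rat357, those of the spread of each tissue not being refitted.

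Gene levels in rats that breathed air also differed between the times. Outside the olfactory bulb, whose 1 h and 24 h numbers were interleaved, rat numbers ran mostly in blocks by time. Each rat was sampled at 1 time. A difference between times thus cannot be told apart from one between sets of rats or their handling. In brain stem Macir, which dampens inflammation, was higher and Wbp2, a coactivator, lower at 24 h. In the olfactory bulb Slc34a1, a phosphate transporter, and Cox5a, a subunit of cytochrome c oxidase, were lower at 6 and 24 h. At 1, 3, 6 and 24 h the Air means were 3.08, 3.17, 3.13 and 4.26 for Macir (adjusted p = 1.8e-06), 8.45, 8.55, 8.54 and 7.78 for Wbp2 (adjusted p = 2.9e-06), 7.77, 7.80, 5.66 and 6.26 for Slc34a1 (adjusted p = 1.1e-11) and 7.13, 7.09, 5.65 and 5.86 for Cox5a (adjusted p = 2.0e-09). Gmppa, of sugar nucleotide supply, had 7.11, 6.73, 8.27 and 8.20 in heart (adjusted p = 1.2e-06), Vps28, of endosomes, 9.88, 9.57, 10.26 and 10.24 in lung (adjusted p = 5.6e-04), and Alx1, a homeobox factor, 6.33, 6.10, 5.42 and 5.12 in kidney (adjusted p = 0.00688). Such differences were called for 2420 probe sets in brain stem, 3777 in lung, 433 in olfactory bulb, 170 in heart, 1 in kidney and 0 in blood, where limma gave 1350 at an unadjusted p under 0.05. RNA quality moved with time as well: the 3′ index of the Air rats had means of 0.217, 0.445, 0.191 and 0.139 in lung and 0.516, 0.51, 0.319 and 0.389 in olfactory bulb. With it as a covariate the counts were 0 in lung, 172 in olfactory bulb, 407 in heart and 2 in kidney. Vps28 was then not called (adjusted p = 0.162), and Slc34a1 and Cox5a were (adjusted p = 4.6e-08 and 5.1e-07). In brain stem the count was 0 without the 24 h Air arrays, and in lung 0 without the 3 h Air arrays, both chosen after the data were seen. Leaving out Air Rat355 gave 1821 in lung, and Air Rat328 and Rat502 gave 1314 and 1355 in brain stem. In heart the count was 62 to 113 without 1 of Air Rat382, Rat355, Rat370, Rat388, Rat335, Rat353, Rat352, Rat377, Rat354 and Rat345, from lowest to highest. In kidney it was 2 without Air Rat345, Rat353, Rat354, Rat365 or Rat388 and 5 without Air Rat490.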

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

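The tests of RNA quality, cell markers, time of day, handling and the identity of Rat351 below, the splits for the difference between tissues, the count of draws that repeat the real split, and the test with the spread of each tissue were chosen after the results were seen.

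The lung at 3 h gave the most calls of the 24 contrasts, and the Air rats of that time had the highest mean 3′ index of the lung groups. For 79.7% of the 3071 called probe sets the Air 3 h mean lay farther from the other Air groups than the PH3 3 h mean did, which a lower RNA quality of these Air samples needs, and it may explain many of the calls. A linear trend with the index cannot be told apart from an effect of phosphine, since the median called effect fell from 0.467 to 0.314 (67.2% left) and its SE rose from 0.12 to 0.157, so most calls ended. Fewer blood and connective tissue cells in the Air 3 h lungs would lower the markers of all 6 such cell types. Their medians, Air 3 h minus the other Air groups, ran from -0.716 for NK cells to 0.00742 for B cells, which argues against a loss of all of them alike and leaves NK cells or other single types open. An effect of phosphine stays open for genes such as Il1r2 (with the other Air arrays as controls it was among 185 probe sets called alike).

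The brain stem arrays of 24 h stood apart in both exposures, 7 of 8 of them beyond 5 robust SDs on the first component. RNA quality along the 3′ index is argued against, as 1769 probe sets differed between the Air times with the index as a covariate, 1698 of them among the 2420 that differ without it. The time of day is argued against as the main cause, as 11.1% of clock genes differed between 24 h and 1 h in air, against 9.53% of all genes, and 0 of 18 in the kidney of the same rats, though 5 of 18 differed between any of the Air times in brain stem, so a part of it stays open. A state of the whole rat that changes all tissues to a like extent is argued against. Between 24 h and 1 h in air 2407 probe sets differed in brain stem, against 17 in heart, 2 in kidney and 13 in lung. At most 0.208% of the 2407 differed alike in heart, kidney or lung, a share that these few calls cap. In lung 5 of the 13 were shared with brain stem, so a part of such a state stays open. Samples handled apart at 24 h cannot be told apart from a change in the brain stem, since all 24 h samples share the time, and this could act on Air and PH3 alike.

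Leaving out PH3 Rat343 lowered the 1 h counts most in heart (85), kidney (396) and lung (769), and as much as leaving out Air Rat352 in brain stem (32). This was not examined further. Leaving out PH3 Rat351 at 1 h (766 in heart, 129 in blood) or PH3 Rat333 in blood at 24 h (172) raised the counts most. An exchange of the blood samples of Rat333 and Air Rat328 is argued against, as 2 of 2 arrays correlated best with the other tissues of their own rat. That Rat351 breathed air or that its arrays are of different rats is argued against, as its glucocorticoid score lay above every Air rat in 4 of 4 tissues and 5 of 5 arrays matched their own rat. Lower RNA quality of its arrays is argued against, as its index was the highest of the PH3 rats in 0 of 5 tissues. Its score was the lowest of the PH3 rats in 4 of 4 tissues, which restates why the rat was picked and is no further evidence, and a weaker response or a lower dose taken in stays an untested hypothesis.

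In 25 of 416 groups of 4 or 5 rats the highest or lowest rat lay apart for a named gene by more than Dixon's 95% limit on its gap over the range of the group; chance flags about 1 in 20 groups, 20.8 here. Rat351 was that rat in 11. At 1 h these were Sgk1 in brain stem (0.923), Atf3 (0.858), Fosb (0.863) and Sgk1 (0.892) in heart, Maff (0.935), Mt2A (0.871), Dhcr7 (0.944), Tnfrsf12a (0.873) and Itgb3 (0.91) in kidney, Edem1 in lung (0.872) and Nr4a3 in blood (0.918). Other PH3 rats at 1 h were Rat357 for Ahr (0.942) and Rat350 for Gadd45a (0.848) in lung, and Rat506 for Cebpb (0.86) and Rat483 for Atf3 (0.854) in olfactory bulb. Air rats at 1 h were Rat345 for Evi2a (0.838) and Per1 (0.879) in kidney and Per1 in heart (0.906), Rat353 for Slc7a5 (0.868) and Hk2 (0.846) and Rat354 for Fosb (0.903) in lung, and Rat472 for Errfi1 in olfactory bulb (0.712). In lung at 3 h they were PH3 Rat368 for Hmcn1 (0.93), Air Rat355 for Hspg2 (0.843) and Air Rat370 for Dnajb9 (0.848). For the 3′ index, 5 of 47 groups had such a rat: heart PH3 1 h Rat357 (0.894), lung Air 1 h Rat354 (0.884), heart PH3 3 h Rat368 (0.832), blood PH3 6 h Rat381 (0.919) and brain stem Air 6 h Rat394 (0.887).

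The effect of phosphine differed between times for 22 probe sets in brain stem, 36 in heart, 152 in kidney and 1497 in lung. It differed between tissues for 1981, 243, 235 and 901 probe sets at 1, 3, 6 and 24 h in the fit of all arrays. Of 97 control probe sets of the array, 5 were called in the lung at 3 h and 0 in the other 23 contrasts.

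Other splits of the same rats were fitted in the same way. At 1 h in brain stem (95, highest other split 1), heart (284, 25), kidney (729, 65) and lung (1317, 157), 1 of 35 splits, the real one, gave as many. These tissues come from the same rats at 1 h, so they show the same split and not separate ones. The same share held at 3 h for kidney (94, 5) and lung (3071, 6). Brain stem (5, 1) and heart (2, 1) at 3 h, kidney (5, 1) at 6 h and heart (2, 1) at 24 h also had 1 of 35. A share of 1 of 35 is the smallest these groups allow and is not adjusted over the 24 contrasts. It cannot exclude chance by itself, for large counts either, and it is weakest for counts of 5 or fewer. The calls in brain stem and heart at 3 h, kidney at 6 h and heart at 24 h were 0 with the 2 groups alone. Chance cannot be excluded for brain stem at 24 h (1, highest other 29), where 18 of 35 splits gave as many, or for olfactory bulb at 1 h (1, highest other 56), where 14 of 100 did. Where 0 were called, every split gives as many (35 of 35 in each contrast), so this test says nothing there: the highest other was 5, 0, 1 and 2189 in blood at 1, 3, 6 and 24 h, 1 in brain stem and 41 in heart at 6 h, 1 in kidney at 24 h, 2 and 9 in lung at 6 and 24 h, and 1, 1 and 0 in olfactory bulb at 3, 6 and 24 h. The 2189 in blood exchange Rat333 and Rat328, and an exchange of these 2 samples is argued against above. This count, the 41 in heart and the 29 and 56 above can point to another structure of the samples, which was not tested.

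For the difference between times of the effect, labels were dealt again within each time, which removes the effect at all times. These splits test for no effect at all, not for an effect equal at all times. They thus cannot exclude chance for the time dependence itself. In brain stem (22, highest other 5), heart (36, 24), kidney (152, 106) and lung (1497, 286) 1 of 100 splits, the real one, gave as many. In blood (0, 1923) and olfactory bulb (0, 2) the real count is 0, so 100 of 100 splits give as many and the test says nothing. Between Air times chance can be excluded in brain stem (2420, 4), heart (170, 6), lung (3777, 1689) and olfactory bulb (433, 75), and not in kidney (1, 4), where 9 of 100 gave as many. In blood (0, 4) the test says nothing. For the glucocorticoid targets at 1 h the real camera p was 4.3e-05 in brain stem, 6.5e-05 in heart, 4.1e-06 in kidney and 3.3e-05 in lung. The smallest of other splits was 0.00103, 0.00221, 0.00163 and 0.00163. Only the real split of 35 gave so small a p in each tissue, the smallest share these groups allow. The tissues share the same rats and split, so this cannot exclude chance by itself. For the genes shared by 4 tissues 3 of 100 splits gave as many (4, highest other 4). The 2 others deal the rats of these tissues as in the real split or its mirror and differ in the olfactory bulb rats at most. The remaining 97 gave at most 0. The rats of these tissues allow 35 different splits, so these draws repeat them and the smallest possible share stays 1 of 35. This too cannot exclude chance by itself.

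For the difference between tissues, labels dealt again remove the effect in all tissues. These splits test for no effect at all, not for an effect alike in all tissues, so they cannot exclude chance for the tissue dependence itself. In the fit of all arrays 4, 10, 25 and 23 of 50 splits gave as many at 1, 3, 6 and 24 h (highest other 2040, 1257, 1699 and 5043). At 1 h, 2 of the 3 other draws as large deal the rats that gave a heart as in the real split or its mirror. With array weights only the real split gave as many at 1 h (1320, highest other 1280, 1 of 50), and at later times 4, 26 and 12 of 50 did (highest other 589, 1689 and 1633). With the spread of each tissue only the real split gave as many at 1 h (959, highest other 877) and 3 h (94, 26), and at 6 h (2, 621) 3 of 50 did. The 1280 and the 877 at 1 h also come from draws that deal the rats that gave a heart as in the real split or its mirror. Among the draws that do not, the highest were 642 with array weights and 144 with the spread of each tissue. At 24 h (0, 768, 50 of 50) the real count is 0 and the test says nothing. Splits that call many more than the real one can point to structure of the samples, which was not tested.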

How the results depend on the processing

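The 3′ index as a covariate, leaving out arrays that stand apart, the other controls and times, the tissue test without blood and the test with the spread of each tissue were chosen after the data were seen. The deposited values give no signal over background per probe set, so dim probe sets, where the change on the log scale is compressed, limit what can be called. With 4 rats per group an adjusted p rests on the spread shared by the 8 groups of a tissue, and the cause of the changes below was not tested unless stated. Counts are of called probe sets, with the reported count first where given.

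With the groups of a contrast alone, which leaves 6 residual degrees of freedom, the counts at 1 h were 18 in brain stem, 9 in heart, 121 in kidney, 519 in lung and 0 in olfactory bulb. At 3 h they were 0 in brain stem, 0 in heart, 14 in kidney and 801 in lung, at 6 h 0 in kidney, and at 24 h 0 in brain stem, 0 in heart and 2 in kidney.

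In the fit with the rat as replicate block all tissues share 1 estimate of the spread, which raises counts in tissues with a large spread by construction. The counts at 1, 3, 6 and 24 h were 6015, 1987, 3322 and 5686 in blood and 7, 36, 29 and 3 in olfactory bulb. The median residual SD was 0.159 in olfactory bulb, against 0.491 in blood. That median is over all probe sets and does not give the spread of the few called in the bulb. Whether a large spread at those accounts for the higher counts was not tested. At 1, 3 and 24 h they were 18, 0 and 6 in brain stem, at all times 733, 25, 3 and 101 in heart, and at 1, 3 and 24 h 214, 31 and 2 in kidney. In lung they were 384 at 1 h, 3.9e+02 at 3 h (188 higher, 200 lower) and 9 at 6 h.

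A mean-variance trend with robust moderation called 5 in blood at 1 h, and no other count moved by over 1.5 times. With the brighter 50 percent of probe sets, blood had 4 and olfactory bulb 0 at 1 h, olfactory bulb 1 at 3 h and kidney 11 at 6 h. Between Air times kidney then had 3 and olfactory bulb 1.9e+02, and between tissues the counts were 63 at 3 h and 81 at 6 h. Quantile normalization again gave 1 in heart at 24 h and 0 in olfactory bulb at 1 h. With array medians subtracted, blood had 4 at 1 h and brain stem 0 at 24 h. The number range as a block left 0 in olfactory bulb at 3 h and 6 h.

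With 1 probe set per gene fewer are tested, so lower counts follow in part from the construction. Brain stem had 48, 2 and 0 at 1, 3 and 24 h, heart 1 and 1 at 3 and 24 h, kidney 407 and 3 at 1 and 6 h, lung 795, 1253 and 1 at 1, 3 and 6 h, blood 3 and olfactory bulb 0 at 1 h. Effects that differ between times were 13 in brain stem, 89 in kidney and 797 in lung, and between Air times 1347 in brain stem, 2028 in lung and 96 in olfactory bulb.

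With the 3′ index as a covariate, brain stem had 0 at 24 h and lung 4 at 3 h and 1 at 6 h. Effects differed between times for 95 in heart and 535 in lung, and Air times differed for 407 in heart, 2 in kidney, 0 in lung and 172 in olfactory bulb. Without the arrays that stand apart, heart had 177, 0 and 1 at 1, 3 and 24 h, lung 1739 at 3 h, and olfactory bulb 0 and 1 at 1 and 3 h. With the other Air arrays as controls, lung at 3 h had 431, and C3h20orf96 (0.01) and Dcn (-0.073) changed sign. Without the 24 h Air arrays 0 probe sets differed between Air times in brain stem, and without the 3 h Air arrays 0 in lung.

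Lists called by camera were 4 in blood, 14 in brain stem, 21 in heart, 17 in kidney, 22 in lung and 32 in olfactory bulb. With an estimated correlation they were 0, 2, 2, 4, 1 and 0, and with fry 0, 2, 4, 5, 12 and 0. With all probe sets of the members they were 13 in blood, 26 in kidney and 39 in lung.

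Between tissues, array weights gave 1320, 372, 12 and 64 at 1, 3, 6 and 24 h, and the spread of each tissue 959, 94, 2 and 0. Without the olfactory bulb the counts were 132 at 3 h and 94 at 6 h, and without blood 7 at 6 h and 46 at 24 h. Genes shared by tissues at 1 h were 4, against 33 in at least 3 tissues, 0 in at least 5, 1 at an adjusted p under 0.01 and 7 with all probe sets. At 3 h they were 0, against 1 in at least 3 tissues and 1 with all probe sets.

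Leaving out 1 rat in turn gave these lowest and highest counts of called probe sets. In blood they were 0 and 129 (without PH3 Rat351) at 1 h and 0 and 172 (PH3 Rat333) at 24 h. In brain stem they were 32 (PH3 Rat343 or Air Rat352) and 112 at 1 h, 0 (PH3 Rat358) and 5 at 3 h, 0 and 1 (PH3 Rat375) at 6 h, and 0 (PH3 Rat325) and 3 (PH3 Rat326) at 24 h. In heart they were 85 (PH3 Rat343) and 766 (PH3 Rat351) at 1 h, 0 (PH3 Rat359) and 2 at 3 h, and 0 (Air Rat328) and 5 (PH3 Rat325) at 24 h. In kidney they were 396 (PH3 Rat343) and 993 at 1 h, 32 (PH3 Rat363) and 93 at 3 h, and 2 (PH3 Rat391) and 6 at 6 h. In lung they were 769 (PH3 Rat343) and 1488 at 1 h, 1356 (PH3 Rat368) and 3265 at 3 h, and 0 and 3 (Air Rat340) at 24 h. In olfactory bulb they were 0 (PH3 Rat482) and 3 (PH3 Rat506) at 1 h, 0 and 8 (PH3 Rat399) at 3 h, and 0 and 8 (PH3 Rat387) at 6 h.

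For effects that differ between times, leaving out 1 rat gave 0 and 2 (PH3 Rat351) in blood, 11 (PH3 Rat343) and 42 (PH3 Rat351) in brain stem, 10 (PH3 Rat343) and 186 (PH3 Rat351) in heart, 110 and 280 (PH3 Rat351) in kidney, and 908 (PH3 Rat368) and 1762 in lung. Between Air times it gave 1314 (Air Rat328) and 2646 in brain stem, 62 (Air Rat382) and 225 in heart, 1 and 5 (Air Rat490) in kidney, and 1821 (Air Rat355) and 4032 in lung. Between tissues it gave 1089 (PH3 Rat357) and 3282 (PH3 Rat351) at 1 h, 163 and 3.7e+02 (PH3 Rat399, rounded) at 3 h, 136 (PH3 Rat381) and 582 (PH3 Rat387) at 6 h, and 262 (PH3 Rat341) and 3318 (PH3 Rat333) at 24 h. Other rats that moved these by over 1.5 times were PH3 Rat343 (1282) at 1 h, PH3 Rat375 (3.6e+02, rounded) and Air Rat382 (145) at 6 h, and PH3 Rat326 (595), Air Rat328 (2336), Air Rat335 (278) and Air Rat340 (466) at 24 h. Lists called ran from 3 to 11 (PH3 Rat341) in blood and from 9 (Air Rat355) to 17 in brain stem.

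Of 208 effects of named genes, 111 lost their call with the groups of a contrast alone, 72 with the rat as replicate block (3 gained one), 34 with the 3′ index, 7 with array medians subtracted, 3 with quantile normalization again and 2 with a trend and robust moderation. Without the arrays that stand apart 28 of 121 lost it, and with the other controls 25 of 31. Leaving out a rat ended 313 of 1676. Of 110 list calls, 101 were lost with an estimated correlation, 92 with fry, 11 with all probe sets and 168 of 886 on leaving out a rat.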

Other observations

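The match of arrays to rats and the look at other groups of genes in this part were chosen after the results were seen, though the lists themselves were fixed earlier.

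At 1 h the lists of cytochrome c oxidase, NRF2, hypoxia and p53 below were not called in camera, while single members of the last 3 passed. In the solid tissues with most calls, the 13 subunits of cytochrome c oxidase, the enzyme that phosphine blocks, had 0 called, with a median effect of -0.01 in heart (camera adjusted p = 0.985), -0.02 in kidney (0.984) and 0.12 in lung (0.501); with an estimated correlation the adjusted p was 0.991, 0.993 and 0.995. Of 17 genes of NRF2 and glutathione, which handle oxidants, 1 was called in lung, Txnrd1, a reducer of thioredoxin, by 0.28 (list adjusted p = 0.114). Of 24 targets of hypoxia, 2 were called higher in kidney (0.0749) and 2 higher and 1 lower in lung (0.0773). Of 14 p53 targets, 3 were called higher in brain stem, 2 in heart, 3 in kidney and 3 in lung, at list adjusted p of 0.142, 0.245, 0.0775 and 0.105. Cdkn1a was among those in brain stem, kidney and lung. The other respiratory chain and ATP synthase subunits were called at 1 h in lung, median 0.10, 23 of 24 positive (camera adjusted p = 0.0326, adjusted p = 0.98 with an estimated correlation; lost without PH3 Rat351 or Rat357 or Air Rat345 or Rat352), and in olfactory bulb, median -0.04, 17 of 24 negative (0.0497 and adjusted p = 0.774 with an estimated correlation; lost without any 1 of 6 rats). A p that misses the threshold does not show that a group did not change.

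At 24 h several groups of genes shifted in camera. In heart, cholesterol synthesis had a median effect of -0.46, 13 of 15 genes negative (camera adjusted p = 2.1e-06, adjusted p = 0.555 with an estimated correlation; lost without Air Rat340), and 15 of 15 macrophage markers were positive, median 0.44 (4.5e-05 and adjusted p = 0.759 with an estimated correlation). In lung, T cell and B cell markers had medians of 0.35 and 0.30 (7.9e-08 and 5.7e-04, adjusted p = 0.3 and 0.43 with an estimated correlation), and proliferation genes -0.30 (4.4e-06 and 0.612). Glucocorticoid targets, higher at 1 h, had a median of -0.20 in brain stem, -0.24 in lung and -0.11 in kidney at 24 h (6.8e-04, 5.8e-05 and 0.0247, adjusted p = 0.677, 0.391 and 0.485 with an estimated correlation). The kidney call was lost without PH3 Rat333 or Air Rat335 or Rat502. In olfactory bulb this list was also called at 24 h (camera adjusted p = 0.00679), but not with an estimated correlation, in fry or without PH3 Rat488 or Air Rat502.

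Of the 165 arrays with other tissues of their rat, 163 matched their own rat best. The heart array of Air Rat370 at 3 h had a correlation of 0.0524 with its own rat and 0.178 with its best match, and the heart array of PH3 Rat368 at 3 h had 0.656 with its own rat and 0.722 with the kidney array labelled Rat363. That kidney array is the only one of its number and matched Rat368 at 0.777, with 0.245 as its second best, so Rat363 and Rat368 may be 1 animal under different numbers. No kidney array is labelled Rat368, so the group holds 4 animals either way, and leaving out this array gives 32 calls in the kidney at 3 h.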
